A study of Homo sapiens with 4 samples.

How the data were processed

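RNA of 4 cultures of 22Rv1 cells was labelled with an Affymetrix whole-transcript kit and hybridised to 1 array per group, per the labels' protocols. The deposited values are log2 expression signals that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes, with versions not given in the sources used here. RMA subtracts background, forces the arrays to a common distribution and summarises probes, so a global change of RNA content cannot be seen. The log base was read from the range of the values, and 327 to 379 values per array exceeded 16, above the log2 range of a 16-bit scanner, so the scale may be stretched and folds hold on the deposited scale only. The genome build is not given in the sources used here, and no coordinates are printed.

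Of 24351 probe sets, 17709 had 1 gene symbol in the platform table, 0 had several, 3739 transcript probe sets were unnamed here, and 2197 positive, 612 negative and 94 other control probe sets were kept apart. These gave 17687 genes, 20 of them with more than 1 probe set, of which the one with the highest mean was used. A gene counted as measured where its highest value exceeded the median of that value over all genes, 6.51. Background was the 95th percentile of the negative control probe sets of each array, 6.62 and 6.99 for siControl in vehicle and DHT and 7.39 and 6.91 for siOCT1. Where the dimmer array of a pair lay below its own background, the brighter value over that background is given as "at least N-fold", and no fold is given where both lay below it.

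Groups came from the labels. Differences between single arrays were counted at 1.5-fold in either direction, and genes past this in both pairs of arrays were set beside the overlap of independent lists. An additive model of siRNA and ligand was fitted over the 4 arrays with limma 3.58.1 (lmFit, eBayes with an intensity trend) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, and "rose" and "fell" are used of genes it called. It has 1 residual degree of freedom and a prior of 5.85, and assumes that both effects add, so a gene with an interaction inflates its residual. In addition, 20 gene lists were fixed before the data were examined: OCT and POU factors, androgen-induced and androgen-repressed genes, mitosis, DNA replication, DNA repair, histone H2B, p53 target, unfolded protein and amino acid stress, interferon-stimulated, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, neuroendocrine and immediate early genes, luminal epithelial markers, basal, stromal and immune markers, ribosomal protein genes, reference genes, and 1 list left out of the text. Each median was placed among 10000 random lists drawn within 100 expression ranks of each member, as a description of these arrays.

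Named genes were the 10 highest and 10 lowest by mean difference among measured genes past the size rule in both pairs, the 5 highest and 5 lowest for the change of the DHT response, and up to 3 members per list with the largest mean difference. POU2F1 and FKBP5 were not analysed here, and TMPRSS2 lay under the measured level. Data were simulated for the siRNA comparison with 200 changed genes among 8843, equal Gaussian noise for every gene (standard deviation 0.30) and no interaction. The size rule recovered 71.5% of 2-fold changes with 139 false genes, and limma 32.0% with 1. Both recovered 100% of 8-fold changes, with 126 and 10 false genes. On the real arrays 18.6% of the negative controls passed the size rule in both ligand states, so these false counts do not carry over to dim genes.

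Alternatives fixed together with the lists were a 2-fold rule, no filter and a stricter filter on dim genes, the mean of probe sets, loess centring along expression, 32 added before the logarithm, limma without trend or with robust moderation, and leaving out small RNA and uncharacterised symbols. Raising values to background and centring on the positive controls were added after seeing the data. Background was first raised array by array, and because the 4 levels differ by up to 0.77, more than the size rule, a single level was then used as well. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 did the rest.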

Results

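Total RNA of 22Rv1 cells, a human castration-resistant prostate cancer line, was profiled on 4 whole-transcript arrays. Cells received a control siRNA (siControl) or an siRNA against OCT1 (siOCT1), the octamer-binding transcription factor encoded by POU2F1, and then ethanol vehicle or 10 nM dihydrotestosterone (DHT) for 24 h. Each of the 4 groups held 1 array, so no difference below has a replicate check, and the number of arrays limits the precision. The design asks which genes respond to androgen in these cells and how those responses look once OCT1 is targeted. The level of POU2F1 itself was not analysed here, so the depletion was not checked and siOCT1 stands for the transfection as labelled. Signals had medians of 5.99 to 6.03 on the log2 scale and correlated between arrays with Pearson r of 0.963 to 0.986 across probe sets. Of 17687 named genes, 8843 counted as measured, and 6458 genes lay above the background of the negative control probe sets on every array. Differences are log2 values on the deposited scale.

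Genes of DNA replication and cell division had lower signal in siOCT1 cells. RRM1, the large subunit of ribonucleotide reductase, fell by 4.15 in vehicle and by 3.88 in DHT. CDC45, a component of the replicative helicase, was at least 15.6-fold lower in vehicle and fell by 3.81 in DHT, and cyclin A2 (CCNA2) fell by 4.01 and 3.74. SEPTIN4, a septin GTPase, was at least 25.7-fold lower in vehicle and at least 39.2-fold lower in DHT, bounds set by the background of the siOCT1 arrays. On the other side, PNRC1, a nuclear receptor coregulator, rose by 3.73 and 4.32, and ARHGAP29, a GTPase-activating protein, by 3.94 and 3.71.

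Among the 10 genes with the highest mean difference, AKR1C2, a hydroxysteroid dehydrogenase of the aldo-keto reductase family, rose by 4.14 in vehicle and 4.92 in DHT. AKR1C1 rose by 4.29 in vehicle and was at least 5.03-fold higher in DHT, and AKR1C3 was at least 8.91-fold and 4.14-fold higher. UGT2B15, which glucuronidates androgens, was at least 15-fold and 2.69-fold higher. These genes have near-identical paralogs whose probes can share transcripts, so the signal of each is uncertain. Sucrase-isomaltase (SI) was at least 40.8-fold higher in vehicle and 2.02-fold in DHT, and the cholesterol exporter ABCA1 at least 4.87-fold and 2.57-fold. HMOX1, the inducible haem oxygenase, was at least 11.1-fold and 3.50-fold higher, and the RNA-binding protein gene A1CF at least 10.1-fold and 4.03-fold.

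The other lowest genes were DHRS13, at least 18.9-fold lower in vehicle and 20.2-fold in DHT, GGCT, at least 12.2-fold lower in vehicle with a fall of 3.77 in DHT, and OXCT1, a ketone-body enzyme, at least 11.4-fold lower with a fall of 3.88. SNAI2, a zinc finger repressor of epithelial genes, fell by 4.08 in DHT and was at least 1.90-fold lower in vehicle. GNAZ lay below background on 3 arrays. FAM72A and FAM72C, near-identical copies that the probes may not separate, fell by 3.76 and 3.86 in vehicle.

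Across measured genes, 1080 were higher and 1652 lower by at least 1.5-fold in both ligand states, against 382.7 and 661.5 for independent lists, and 85 passed the size rule in opposite directions. The 2 differences shared no array and correlated with Pearson r of 0.76 and Spearman correlation of 0.73 across genes, which are not independent replicates. The excess of lower genes in both ligand states shrank to 1275 higher and 1421 lower with arrays centred on positive controls. With loess centring the counts were 1286 and 1463. In vehicle alone 2024 genes were higher and 2541 lower, a balance that turned to 2752 and 1961 with arrays centred on positive controls, and in DHT 1672 and 2302. The additive limma fit called 805 genes higher and 1353 lower after Benjamini-Hochberg adjustment, RRM1 with an adjusted p of 0.000843. Its residual is the siRNA-by-ligand difference on 1 degree of freedom, not the spread between repeat cultures, and with values raised to the highest background of the 4 arrays it called 1405 genes in all. Of the 612 negative control probe sets, 18.6% also passed the size rule in both ligand states, and 32 of the 87 bright enough to count as measured did, 36.8% against 30.9% of measured genes, so counts of dim genes include noise.

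**Figure D1:**
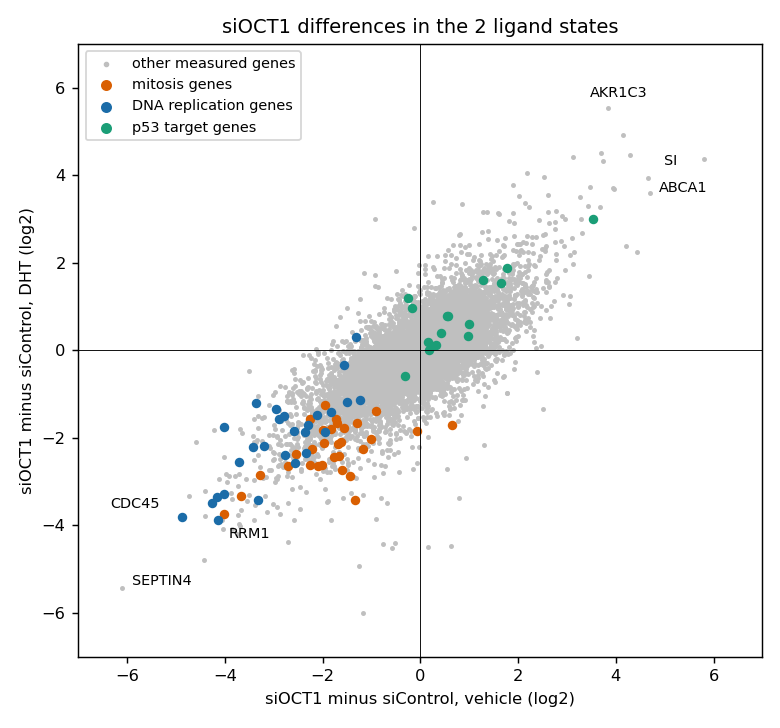
Each point is a measured gene, with the siOCT1 minus siControl difference in vehicle on the x axis and in DHT on the y axis, both in log2 units. Mitosis, DNA replication and p53 target genes are coloured, and the mitosis and replication groups have medians of -1.98 and -2.28 for the mean of both axes.

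The mitosis list fell nearly as a whole, with 28 of 30 measured genes lower in the limma fit and a median of -1.74 in vehicle and -2.20 in DHT. CDC20, the activator of the anaphase-promoting complex, fell by 3.67 and 3.32, and the kinetochore gene NDC80 fell by 2.84 in DHT and was at least 7.67-fold lower in vehicle. Of 27 measured DNA replication genes 25 fell, 26 when adjusted over the list alone, with medians of -2.79 and -1.86. The flap endonuclease FEN1 was at least 13-fold lower in vehicle and fell by 3.49 in DHT. Of 16 measured DNA repair genes 10 fell (11 when adjusted over the list alone), among them XRCC2 by 2.98 and 3.01, with a median of -1.91 over both ligand states. Of 11 measured H2B histone genes 8 fell (10 when adjusted over the list alone), with a median of -1.39, H2BC14 by 3.96 and 3.01. Each of these 4 medians lay in the lowest 2.5% of 10000 random lists matched on expression.

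Lipid, glycolysis and endoplasmic reticulum genes were lower as well. Cholesterol synthesis genes had a median of -1.10 with 13 of 19 fallen (14 fallen and 1 risen when adjusted over the list alone), ACAT2 by 2.93 and 1.97 and FDPS by 2.12 and 1.80. Fatty acid synthesis genes had a median of -1.24 with 6 of 10 fallen (7 when adjusted over the list alone), among them the desaturase SCD by 2.78 and 1.45 and the regulator SREBF1 by 2.67 and 1.45. Glycolysis and hypoxia genes had a median of -1.18, with 12 of 19 fallen and 1 risen (14 and 1 when adjusted over the list alone), LDHA falling by 2.24 and 1.66 and BNIP3 by 2.59 and 2.24. Unfolded protein and amino acid stress genes had a median of -0.79 with 9 of 19 fallen (11 when adjusted over the list alone), including the chaperone HSPA5 by 2.20 and 2.47 and MANF by 2.71 and 3.48. The reference genes chosen as housekeeping controls moved too, with a median of -0.64, 4 of 13 fallen and 1 risen (8 and 1 when adjusted over the list alone), PGK1 falling by 2.23 and 0.86. All 5 medians lay in the lowest 2.5% of matched random lists.

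Several lists were higher in siOCT1 cells. Ribosomal protein genes had a median of 0.67 with 10 of 14 risen (12 when adjusted over the list alone), RPS19 by 1.89 and 2.29. The p53 target list had a median of 0.56 with 4 of 16 risen under either adjustment, among them SESN1 by 1.78 and 1.87 and the cell cycle inhibitor CDKN1A by 1.65 and 1.55. Only 7 of the androgen-repressed genes were measured, with a median of 1.31 and 4 risen under either adjustment. UGT2B15, UGT2B17, BCHE and CDH2 lay below background on both siControl arrays. CDH2, whose value is the median, lay below background on both siOCT1 arrays as well, so the size of this median is uncertain. BCHE also lay below background with siOCT1 in vehicle, and UGT2B17 with siOCT1 in DHT. These 3 medians lay in the top 2.5% of matched random lists. Androgen-induced genes had a median of -0.63 in the lowest 2.5%, with 9 of 26 fallen and 3 risen (11 and 3 when adjusted over the list alone), DBI by 2.21 and 1.90 among those that fell. Of the OCT and POU factors 1 gene was measured, POU6F1, which was at least 1.23-fold and 1.21-fold lower and fell under either adjustment.

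The remaining lists had medians outside both the lowest and the top 2.5% of matched random lists. The nuclear receptor corepressor NRIP1 rose by 2.66 and 0.75, and NCOA2 by 1.67 and 0.66, while NR3C1 (the glucocorticoid receptor) was at least 3.03-fold and 1.05-fold higher. Luminal epithelial markers had a median of -0.14 with 2 risen and 2 fallen of 13 under either adjustment, the splicing regulator ESRP1 rising by 1.79 and 1.38 and keratin 8 (KRT8) falling by 0.51 and 1.44. Immediate early genes had a median of -0.05, with 3 of 12 fallen and 1 risen (3 and 2 when adjusted over the list alone), NR4A1 falling by 2.63 in DHT and EGR1 by 1.49 and 1.76. Neuroendocrine genes had a median of -0.19 with 2 of 7 fallen under either adjustment, PEG10 by 0.79 and 2.29 and SYT4 by 1.43 and 0.74. Interferon-stimulated genes, of which 5 of 26 were measured, had medians of -0.074 in vehicle and -0.065 in DHT. Their median of 0.51 over both ligand states is the value of PARP9 alone, at -0.07 and 1.09. No gene was called by limma after Benjamini-Hochberg adjustment, over all genes or when adjusted over the list alone. Of 17 basal, stromal and immune markers 3 were measured, with a median of 0.18 and 1 risen under either adjustment, ACTA2, which was at least 2.19-fold and 1.3-fold higher.

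Several known androgen targets were higher with DHT. The prostein gene SLC45A3 was at least 32.1-fold higher with DHT in siControl cells and at least 28.2-fold in siOCT1 cells. RAB3B, a GTPase of vesicle release, rose by 4.42 and 4.16, and the acetyltransferase NAT1 by 4.26 and 3.42. NT5DC3 rose by 4.50 in siControl and was at least 18.7-fold higher in siOCT1, the amino acid transporter SLC38A4 was at least 8.30-fold and 1.49-fold higher, and the phosphatase INPP4B at least 7.21-fold and 4.49-fold. Tissue factor (F3), GMNC and CHRNA2 were at least 10.7-fold, 4.96-fold and 5.36-fold higher in siControl, and below background on both siOCT1 arrays. The chemokine CXCL13 was at least 2.52-fold higher in siOCT1 and below background on both siControl arrays.

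Genes lowered by DHT included IGFBP3, an insulin-like growth factor carrier, which fell by 4.13 in siControl and 2.60 in siOCT1. TRIB1, a pseudokinase, fell by 3.36 and 2.69, the sialyltransferase ST3GAL1 by 3.04 and 2.27, and the transcription factor GATA2 by 3.26 and 1.93. SI fell by 3.97 in siOCT1 and lay below background on both siControl arrays. The adenylate kinase AK5 was at least 2.45-fold lower in siControl and 7.10-fold in siOCT1, TMEM45A at least 6.82-fold and 2.40-fold, and the prostatic acid phosphatase gene ACP3 at least 1.33-fold and 2.32-fold. BAMBI and MAPK4 were at least 1.78-fold and 2.57-fold lower in siControl and below background on both siOCT1 arrays.

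In all, 430 genes were higher and 386 lower with DHT under both siRNAs, against 196.2 and 132.9 for independent lists, with 124 in opposite directions. The 2 responses, which shared no array, correlated with Pearson r of 0.46 and Spearman correlation of 0.33 across genes. In siControl cells 1396 genes were higher and 1129 lower, and in siOCT1 cells 1243 and 1041, which turned to 1062 and 1240 with arrays centred on positive controls. The limma fit called 60 genes higher and 27 lower after Benjamini-Hochberg adjustment, SLC45A3 with an adjusted p of 0.00057, on the same 1 residual degree of freedom. That total of 87 ranged from 9 with values raised to the highest background to 293 with arrays centred on the positive controls, so this count is fragile. Of the negative controls, 14.7% passed the size rule under both siRNAs, and 27 of the 87 bright ones did, larger shares than the 9.23% of measured genes.

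**Figure D2:**
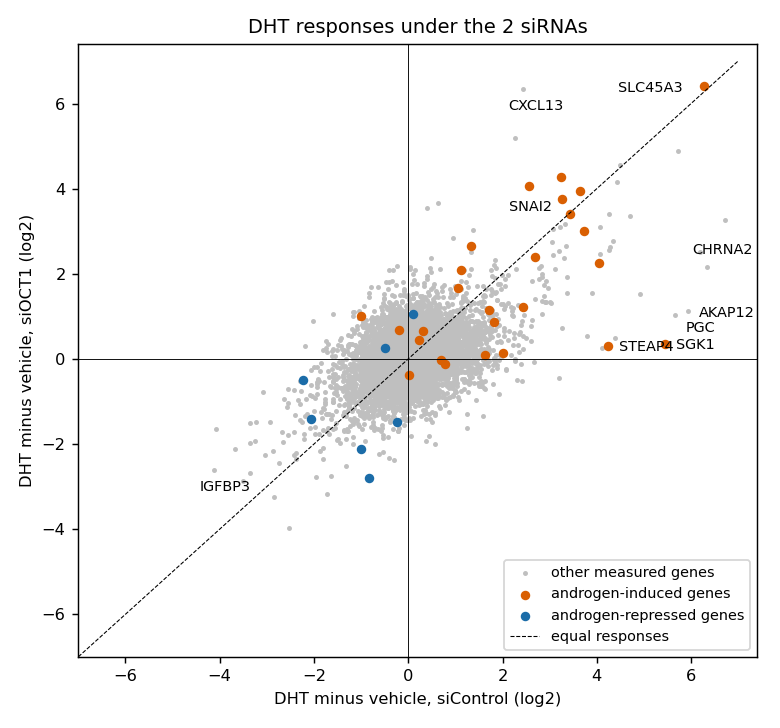
Each point is a measured gene, with the DHT minus vehicle difference in siControl cells on the x axis and in siOCT1 cells on the y axis, both in log2 units, and the dashed line marks equal responses. Points use the deposited values also where these lie below background, as on the vehicle arrays of SLC45A3 and on both siOCT1 arrays of SGK1.

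The androgen-induced list had medians of 1.92 in siControl and 1.19 in siOCT1 cells, both in the top 2.5% of matched random lists, and 15 of 26 measured members were higher by at least 1.5-fold under both siRNAs. In the limma fit 9 rose over all genes tested and 15 when adjusted over the list alone. DBI, the diazepam-binding inhibitor, rose by 3.64 and 3.95, and ZBTB16 by 3.23 in siControl with at least 16.9-fold in siOCT1. KLK3, which encodes prostate-specific antigen, was at least 1.87-fold higher in siControl and lay near background throughout, and KLK2 was higher by 1.32 in siControl with both siOCT1 values below background. The list median of 1.72 over both siRNAs was 0.81 with values raised to the highest background. Androgen-repressed genes had medians of -0.82 and -1.42, in the lowest 2.5%, although 4 of the 7 lay below background on both siControl arrays and CDH2, whose value is the siControl median, on both pairs, with 1 of 7 fallen and 4 when adjusted over the list alone. FOLH1, which encodes prostate-specific membrane antigen, fell by 2.06 and 1.42.

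Mitosis genes had medians of 0.55 and 0.18 and a median over both siRNAs in the top 2.5%, with no member passing the limma test over all genes and 1 when adjusted over the list alone. CDK1 was higher by 1.70 and 1.16. DNA repair genes had medians of 0.60 and 0.40, also in the top 2.5%, with no member passing, and DNA replication genes had medians of -0.15 and 0.62. Ribosomal protein genes had medians of -0.42 and -0.11 and glycolysis genes of -0.54 and 0.08, both with a median over both siRNAs in the lowest 2.5% and no member passing. Among fatty acid genes, with a mean median of 0.11, the elongase ELOVL5 rose by 2.05 and 1.25, the 1 gene called under either adjustment. Of the other lists, H2B histones had a mean median of -0.12, p53 targets 0.02, stress genes -0.02, cholesterol genes -0.00, immediate early genes -0.20 (KLF4 at least 2.84-fold and 2.28-fold higher), luminal markers -0.11 (OCLN falling by 1.83 and 1.38), reference genes -0.11, neuroendocrine genes -0.36, interferon-stimulated genes -0.43 and the basal, stromal and immune markers -0.05. Over all genes limma called 1 luminal marker as fallen and 1 immediate early gene as risen. When adjusted over the list alone these became 3 fallen and 2 risen luminal markers and 2 risen immediate early genes, with 1 fallen p53 target added and none in the other lists. POU6F1 stood at -0.50 in siControl, with both siOCT1 values below background.

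The genes with the largest difference between the DHT responses lay mostly below background on some arrays, and these differences were not tested. SGK1, a glucocorticoid- and androgen-responsive kinase, was at least 4.87-fold higher with DHT in siControl cells, while both siOCT1 values lay below background. The scaffold gene AKAP12, PGC (progastricsin) and the metalloreductase STEAP4 showed the same layout, at least 7.29-fold, 6.53-fold and 2.59-fold higher in siControl and below background in siOCT1. TMEM64 went the other way, with 0.62 in siControl and at least 10.9-fold in siOCT1. CRYM was at least 1.45-fold higher in siOCT1 and below background on both siControl arrays, CRISPLD1 at least 1.55-fold and 3.09-fold higher, and the cadherin CDH6 stood at -2.02 in siControl and 0.90 in siOCT1.

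The response in siOCT1 minus that in siControl was positive by at least 1.5-fold for 1544 genes and negative for 1591 (928 and 2321 with arrays centred on positive controls), a sign that does not tell a larger from a smaller response where DHT lowers a gene. The change was a single value per gene with no test, and 65.2% of the negative controls passed the size rule for it, with 77 of the 87 bright ones, against 35.5% of measured genes. Genes picked as higher in siControl had a median response of 0.97 there and 0.27 in siOCT1, and the mirror selection gave 0.85 in siOCT1 and 0.32 in siControl, so a smaller response on the other siRNA appeared whichever siRNA the genes were picked on. The response was smaller in size for 88.4% of the genes picked on siControl and 73.7% of those picked on siOCT1, an imbalance whose cause was not tested. Within the preset androgen-induced list 14 genes responded less in siOCT1 and 12 more, with a median change of -0.16 with 10.2% of matched random lists lower. Median changes lay in the top 2.5% for DNA replication genes (0.74) and glycolysis genes (0.62) and in the lowest 2.5% for mitosis genes (-0.37).

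**Figure D3:**
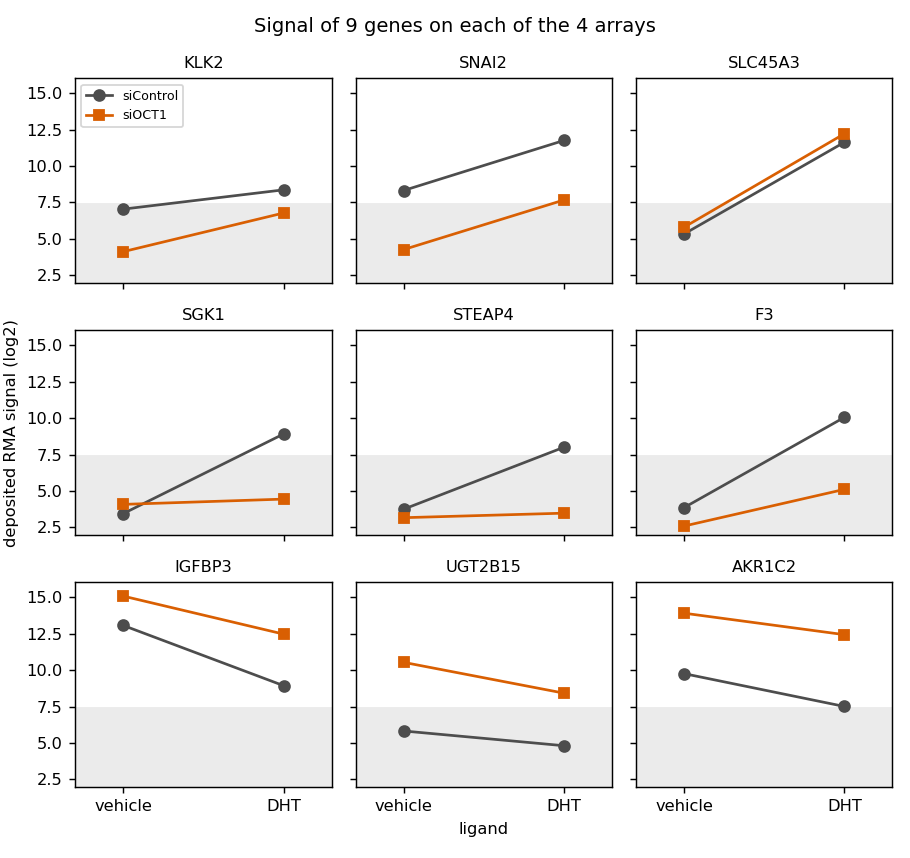
Log2 signal of 9 genes on each of the 4 arrays, with vehicle and DHT on the x axis, circles for siControl and squares for siOCT1, and grey shading up to the highest array background of 7.39. SLC45A3 climbs under both siRNAs, and SGK1 and STEAP4 leave the shading in siControl with DHT alone.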

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

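Loess centring was planned as a processing alternative, but its use as a test of the cell cycle pattern was chosen after the result was seen. So were centring on positive controls, the hormone exposure test, the counts with a single background level, the counts at 4-fold, with and without a length trend, and the comparison of vehicle with DHT arrays. In contrast, those on gene length, the first count of lost responses (related response ratios had already been seen) and the correlation in negative controls were set before.

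With 1 array per group, the opposite differences here were not tested. On deposited values the siOCT1 minus siControl difference was past 1.5-fold in opposite directions in vehicle and DHT for the genes named next. It changed by -3.46 for GMNC, 3.93 for CXCL13, -4.18 for CHRNA2, 2.42 for MAPK4 and -5.09 for SGK1, all below background on 3 arrays. The change was 2.92 for CRISPLD1, -2.35 for HMMR and -1.87 for KLK3, below background on 2 arrays. It was 1.32 for GATA2, above background on every array. For all of these except GATA2, both arrays of a ligand state lay below background, DHT for MAPK4 and vehicle for the others. The difference in that state therefore has no reliable size or direction, and opposite directions are not established for these genes. The DHT response was opposite under the siRNAs for CDH6, with a change of 2.92, and for H2BC8, with 1.499, both above background throughout. In data outside the comparisons, 896 of 3739 unnamed transcript probe sets lay above background on every array, 24.0% against 0.65% of the negative controls, and 248 of them passed the size rule with siOCT1 in both ligand states, 27.7% against 28.1% of named genes so selected. The rule of every array replaced one of any array after the values were seen, under which 346 of 1192 passed, 29.0% against 43.3% of the negative controls.

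The first pattern is the low signal of cell cycle genes in siOCT1 cells, a median of -2.14 over 57 measured mitosis and replication genes. After loess centring the median was -2.06 with an upper quartile of -1.61, which argues against scaling along expression as the whole cause. Centred on positive controls, a single shift per array, the median was -2.04. Of these controls 23.0% passed the siOCT1 size rule in both ligand states themselves, so they are no fixed reference. Random lists matched on gene length had a 2.5th percentile of -0.37, which argues against a length trend. Transfection stress, an off-target effect of the siRNA and culture density stay open, since the siRNAs were given to separate cultures and POU2F1 was not analysed here. Slower proliferation after OCT1 depletion is a hypothesis that was not tested here, and a proliferation assay, another siRNA and the POU2F1 level would decide it.

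The second pattern is the loss of some DHT responses in siOCT1 cells. Over 8-fold higher in siControl and under 2-fold in siOCT1 were 4 genes against 1 in the mirror with array-wise background. That background shrinks the siOCT1 response by construction, and a single background gave 2 against 1. SNAI2, counted as lost under both, responded by 3.43 in siControl and 3.40 in siOCT1 on deposited values. At over 4-fold, a level outside the written prediction, the counts were 38 and 13 with no background level, 40 and 5 array-wise and 25 and 5 with a single background, where selection on arrays of equal noise predicts like counts, but only 19 of the 25 were under 2-fold in siOCT1 before values were raised, and 11 differed between the siRNAs in vehicle alone against 11 in DHT alone. Of 19 androgen-induced genes at least 2-fold higher in siControl, 8 responded as strongly in siOCT1 and 5 by over 1.5-fold more (KLK2 among them below background in siOCT1). A change past 1.5-fold in either direction was seen in 35.5% of measured genes on these single arrays. The test, set after the data were seen, therefore cannot decide on weaker hormone exposure of the siOCT1 culture. The fitted length trend spanned only -0.29 to 0.03 in siControl and left 4-fold counts of 24 and 4. Both argue against a length trend as the whole cause. The -3.94 left for the weakest of 5 losses, picked for size and below background, decides nothing. Unequal array noise, a siControl vehicle array out of line, weaker hormone exposure of the siOCT1 culture and a gene-selective role of OCT1 all stay open.

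The third pattern is that siOCT1 and DHT differences ran in opposite directions, with 154 genes lower with DHT and higher with siOCT1 against 47.1 for independent lists, and 132 in the mirror against 80.3. The mean differences correlated with r of -0.17 across genes, with a covariance of -0.09. Simulating 4 arrays of equal noise and no siRNA or DHT effect gave a covariance of 0.00 and overlaps of 1.07 and 1.10. Equal noise gives a covariance near 0 by design, and without effects few genes pass both rules. The simulated overlaps are therefore no baseline for 154 and 132. In the negative controls r was 0.022, but these carry no transcript, and in the 2197 positive controls, which do, it was -0.135. Unequal array noise that scales with transcripts may therefore account for part of it and cannot be told apart from a shared response.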

How the results depend on the processing

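The tests with values raised to background and with arrays centred on positive controls were chosen after the data were seen. No paired analysis was possible because each group held 1 array and the labels give no replicate numbers. The alternatives gave 2170 values for 135 named genes and 20 lists. Of these, 1887 stayed within the standard deviation of the pair of differences and 280 moved by more. The other 3, which had passed the size rule in both pairs or lay outside the random lists, changed sign. This total overstates the stability. Dropping the filter cannot move a gene's own value, and the mean of probe sets touches 20 genes at most. These settings kept 300 and 309 of 310 values, against 225 with array-wise and 221 with a single background. The reversed ones were the OCT and POU median with siOCT1 at 0.0498 with no filter, where dim genes join the 1 measured, CLDN3 with siOCT1 at 0.27 and LUM with DHT at -0.0591, both with array-wise background, whose levels alone differ by 0.77. In the order siOCT1 in both ligand states, in vehicle, in DHT, then DHT in both siRNA states, in siControl, in siOCT1, then the change, a 2-fold rule left 1292, 2581, 1990, 275, 1028, 723 and 1202 genes, and the stricter filter, which tests 4422 genes, 1515, 2371, 2034, 383, 1226, 926 and 1428. No filter, which tests 17687, gave 5996 for siOCT1 in DHT, 3874 and 4252 for DHT in siControl and siOCT1, and 5985 for the change. Array-wise background left 533 genes for DHT in both siRNA states, and a single background 501, with 1470 for DHT in siOCT1. The limma siRNA effect of 2158 genes was 1405 with a single background. The limma ligand effect of 87 genes was 57 with no filter, 30 without the trend, 258 with array-wise background, 9 with a single background and 293 centred on positive controls; the cause was not tested. Every other count stayed within 1.5 times the main one.

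Centring on positive controls shifted the median of all genes by 0.21 for siOCT1 in vehicle, 0.11 for the mean siRNA difference, 0.15 for DHT in siControl and -0.21 for the change. The share of higher genes among those counted went from 44.3% to 58.4% for siOCT1 in vehicle, from 55.3% to 71.8% for DHT in siControl, from 54.4% to 46.1% for DHT in siOCT1, from 49.2% to 28.6% for the change and from 37.3% to 47.5% for the limma siRNA effect. For siOCT1 in both ligand states that share went from 39.5% to 47.3%, and loess centring gave 46.8%. Array-wise background gave 57.2% and 31.1% for siOCT1 in vehicle and the change, while a single background gave 44.1% and 47.5%. Signal over background limits the dim genes, since 2385 of 8843 measured genes lay below it on at least 1 array.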

Other observations

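All results in this part were chosen after the data were seen. Gene families defined by symbol prefix were read for siOCT1, 42 in all, of which 35 had at least 5 measured genes. Medians of the mean siRNA difference lay in the lowest 2.5% of matched random lists for 13 families, in the top 2.5% for 6 and between for 16, and only families that keep their sign under loess centring and positive-control centring are named here.

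Clustered protocadherins and other PCDH genes were higher in siOCT1 cells, with a median of 1.73 over 15 genes and 10 called higher by limma, although members of the cluster are close paralogs, so single genes are uncertain. HOX genes had a median of 1.03 over 8 genes with 4 called higher. Cytosolic ribosomal protein genes, 51 by prefix, had a median of 0.63 with 30 called higher, while 71 mitochondrial ribosomal protein genes had a median of -0.64 with 20 called lower. Centromere genes (CENP) had a median of -1.57 with 12 of 16 called lower, H2A histones -1.57 with 9 of 13, nucleoporins -0.82 with 8 of 20 and proteasome subunits -0.69 with 14 of 33. Families between these ends included EIF translation factors (-0.24 over 45 genes), USP deubiquitinases (0.17 over 34) and METTL methyltransferases (0.05 over 21).

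Zinc finger genes of the ZNF family had a median change of the DHT response of -0.38 over 305 genes, and aminoacyl-tRNA synthetases 0.78 over 13. Across measured genes the siOCT1 difference had a Spearman correlation with gene length of 0.209 in vehicle and 0.119 in DHT, with medians in vehicle of -0.28 among the shortest genes and 0.18 among the longest, and the change of the DHT response one of -0.159. Matched on gene length instead of expression, the families named at either end kept their place, as did the lists named for siOCT1 and DHT except the reference genes with siOCT1 (3.44% of random lists lower), the single POU6F1 (5.42%) and the ribosomal protein genes with DHT (2.97%).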
